A study of Mus musculus with 7 samples.

How the data were processed

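RNA sequencing of sorted mouse HSCs was analysed from a single table of 33298 genes and 7 libraries, 4 of Dek_fl and 3 of Dek_cKO. Groups and replicate numbers were taken from the sample titles, and 0 columns of per-sample values were left unmapped. The values are FPKM as deposited by the authors, with 1 column per library. Per the submitters' processing notes, Bowtie 0.12.9, Cufflinks 2.1.1 and HTSeq were used with the mouse build mm10. The role of each tool and the version of the annotation are not given in the sources used here. The series text speaks of triplicates, while the labels give 4 control libraries, and all 4 were used.

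Because FPKM are not counts, the main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 libraries were tested, in a model with the group alone, with a mean-variance trend and robust moderation. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 10260 genes tested. Fold changes are Dek_cKO minus Dek_fl on the log2(FPKM + 1) scale, which understates the change of low genes. An exact 0 is reported as listed at 0, since abundant genes are also listed at 0 in single libraries. Dek and the library measures were tested by an exact permutation test of the absolute difference of means over all 35 splits. The 8 library measures were total FPKM, genes above 0, genes at 1 FPKM or more, the shares of the top gene, the top 10 genes and mitochondrial genes, the library total, and the number of abundant genes listed at 0. They were adjusted over these 8.

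The 29 gene lists and the rule for named genes were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 29 lists. The rule named Dek in each library. It then named genes past adjusted p with a mean of at least 2 FPKM in a group, no overlap and an official symbol, up to 10 per direction. Where fewer than 5 passed, the 5 of smallest p without overlap were taken, named as not past the threshold. Some genes that the rule or the lists take are not reported here. From each list it took up to 4 members past the threshold or otherwise the 2 of smallest p, and it added Akt1, Akt2, Mtor, Ncor1, Hdac3, Cdkn1a, Cdkn1c and Ccnb2. Gene positions come from the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes, in which 99.85% of the table's gene identifiers were found. Positions are those of the whole gene, and reads of overlapping genes or near-identical copies, such as ribosomal protein genes, may have been shared by the counting.

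Depth was recovered from the values. FPKM multiplied by the transcript length and by a library total, and divided by a fixed constant, gives whole reads, and the total of each library was the number for which this held. The length was that of the longest annotated transcript, or otherwise the whole-base length up to 3 times as long, plus a margin, that made the values whole. A value was called whole within the rounding to 4 decimals plus 0.003 reads. Genes with at least 30 reads in at least 5 libraries were assessed, and 92.24% of those with whole values were so at the annotated length. Of 47165 assessed values above 0, 46965 were counted as whole. All values of the 21 genes for which no length was fitted were counted as not whole. In a check on simulated data, 288 of 300 single shifted values were found, each in the right library, and 0 of 300 genes with all values shifted fitted a length. Values that were not whole were then read with the totals of the other libraries, with a minimum of 10 reads, to find reciprocal pairs. As a control, 541 genes whose values are whole at a length other than the annotated one were read at the annotated length, and 0 were resolved by exchange. A control gene counted only if separate pairs held all its values that were not whole, which 7 such values cannot meet.

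The limma step was tested on simulated libraries with the means and spread of the real genes, in which 200 of 10260 genes were changed. At the observed spread it found 0 of 200 genes changed by 2 on the log2 scale, with 0 false calls, and 56 of 200 changed by 4, with 2 false calls. At a spread of 25% of that, a simulated setting, it found 175 and 200. Alternatives set before the data were examined were other pseudocounts (0.1 and 0.5), other filters, median-of-ratios scaling, quantile normalization, TPM rescaling, array weights, eBayes without trend or robust moderation, a replicate block and leaving out each library. Alternatives chosen after seeing the data were leaving out the genes that are not whole, exchanging the pairs back with the 3 values of 5 decimals multiplied by 10, and voom on the recovered reads. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.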

Results

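Gene expression was measured by RNA sequencing in hematopoietic stem cells (HSCs) sorted from mouse bone marrow at 12 weeks of age. About 800 cells were sorted for each library by the surface phenotype of long-term HSCs and were amplified from polyadenylated RNA with a low-input kit. The comparison was between mice with floxed Dek alleles and no recombinase, here Dek_fl, with 4 libraries, and floxed mice that also carried Tie2-Cre, here Dek_cKO, with 3 libraries. Tie2-Cre is a recombinase active in endothelial and hematopoietic cells, and DEK is a chromatin-binding protein. Values were FPKM, fragments scaled by transcript length and library depth. The library totals recovered from these values were 4209152, 15653905, 26951515 and 4521306 reads for Dek_fl replicates 1 to 4, and 5950832, 4422645 and 12540431 reads for Dek_cKO replicates 1 to 3. No label states that each library came from a separate animal, so p-values measure the spread between these libraries.

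Libraries of the same group were no more alike than libraries of different groups. Over the tested genes, Pearson's r of log2(FPKM + 1) averaged 0.541 within a group and 0.552 across groups, computed across genes, which are not independent replicates. Dek_fl replicate 4 had 8575 genes above 0, against 14291 to 19950 in the other libraries. Of 1810 genes with a mean of at least 50 FPKM, 101 were listed at 0 in Dek_fl replicate 4 and 9 to 45 in each of the others. Of 8 measures of library depth and composition, each had an adjusted p of 1 and an unadjusted p of at least 0.343 (exact permutation test, two-sided over 35 splits). With so few splits a single measure could not pass after adjustment over the 8. The top gene, Gm23935, took 8.26% to 31.4% of all FPKM in a library, so shares of FPKM are not shares of transcripts. Mitochondrial transcripts took 5.39% ± 4.03 of all FPKM in Dek_fl (SD, n = 4) and 6.13% ± 0.778 in Dek_cKO (SD, n = 3). Dek_fl replicate 4 stood at 11.4% and the other Dek_fl libraries at 2.70% to 4.24%, below each of the Dek_cKO libraries. The difference of 0.737 percentage points was 2.73 without Dek_fl replicate 4 and -0.16 without Dek_fl replicate 3.

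**Figure D1:**
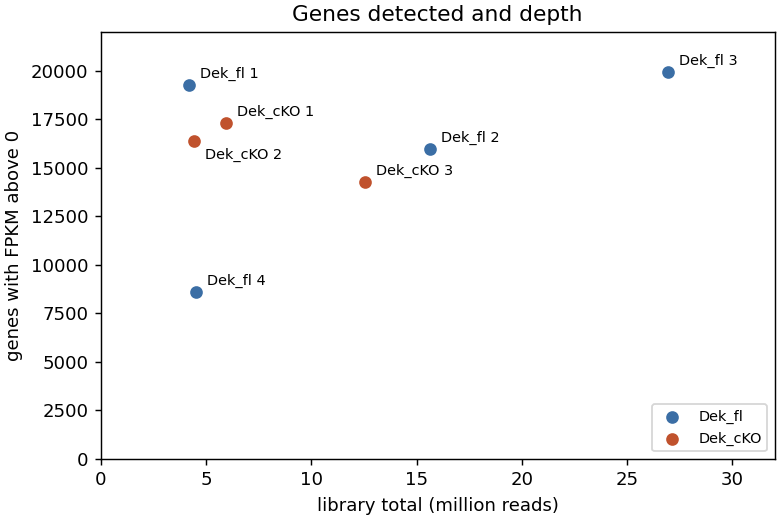
Genes with FPKM above 0 in each library (vertical axis) against the library total of reads (horizontal axis, scaled as labelled). Each point is a library, coloured by group. Dek_fl 4 has 8575 genes at 4521306 reads, while Dek_fl 1 has 19288 at 4209152 reads.

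The question put to these libraries was how loss of Dek alters the transcripts of HSCs, and Dek itself was examined first. Dek, ENSMUSG00000021377 on chromosome 13 from 47084775 to 47106201 of GRCm38, minus strand, stood at 77.0, 117.8, 143.0 and 26.0 FPKM in the Dek_fl libraries. In the Dek_cKO libraries its deposited values were 9.60, 8.40 and 12.7 FPKM. The means were 90.9 ± 51.1 FPKM in Dek_fl (SD, n = 4) and 10.2 ± 2.20 FPKM in Dek_cKO (SD, n = 3), with no overlap between groups. An exact permutation test of the difference of means, two-sided over 35 splits, gave p = 0.0571, where 0.0286 is the smallest p possible. By limma the log2 fold change was -2.81 (SE 0.962), with an adjusted p of 0.9999.

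The deposited value of Dek in Dek_cKO replicate 3 differs from the others in form. It has 5 decimals, as do 3 of the 233086 values in the table, and no other value has more than 4. At the transcript length of Dek, 2556 bases, it stands for 405.8 reads, whereas the other 6 libraries' values of Dek stand for whole numbers of reads. Multiplied by 10 it is 126.6 FPKM and 4058 reads, which lies within the range of the controls. With that value the mean of Dek_cKO was 48.2 ± 67.9 FPKM (SD, n = 3), and the exact permutation test gave p = 0.314. The other values with 5 decimals are those of Gata2, a transcription factor of HSCs, in Dek_cKO replicates 1 and 3, which are also whole reads only when multiplied by 10.

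**Figure D2:**
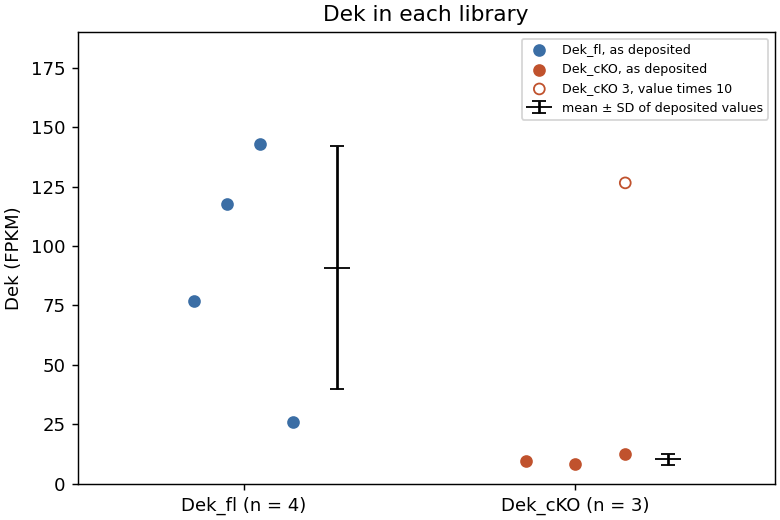
Dek in FPKM (vertical axis) in each library of the 2 groups (horizontal axis). Filled points are deposited values, bars are their mean ± SD, and the open point is the value of Dek_cKO 3 multiplied by 10. The deposited Dek_cKO values lie between 8.40 and 12.7 FPKM, and the open point is at 126.6.

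Whole reads were examined in the same way over the table. Of 7018 genes with at least 30 reads in at least 5 libraries, 6976 (99.4%) had values that were whole reads at a single transcript length in all libraries. The other 42 had values that were not, among them Dek, Gata2, Akt1, Akt2, Mtor, Cdkn1a, Cdkn1b, Rps6, Rpl19 and Rpl36. In 24 of the 42, pairs of values became whole when each was read with the library total of the other, as if the values had changed places. There were 52 such pairs with both values above 0. All 52 joined a Dek_fl and a Dek_cKO column, and in all 52 the higher value stood in the Dek_cKO column. As deposited, all 24 genes were higher in Dek_cKO, with a median log2 fold change of 1.97. Since the higher value of every pair stood in the Dek_cKO column, exchanging pairs back could only lower a fold change. With the pairs exchanged back, 21 were lower and 3 higher, and the median was -1.18. In Nufip1, Sord and Hmgcs1 this included a pair with a value of 0, which is whole with any total. Of the 24 genes, 19 were whole in all libraries after the exchange, Nufip1, Sord and Hmgcs1 only with such a pair. Canx, Rrm2 and Hspd1, the 3 that stayed higher, were among those that keep values that are not whole. Hspd1 was chosen after its values were seen. The cause of these values is not given by the sources used here, and each gene concerned is named as such where it appears.

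**Figure D3:**
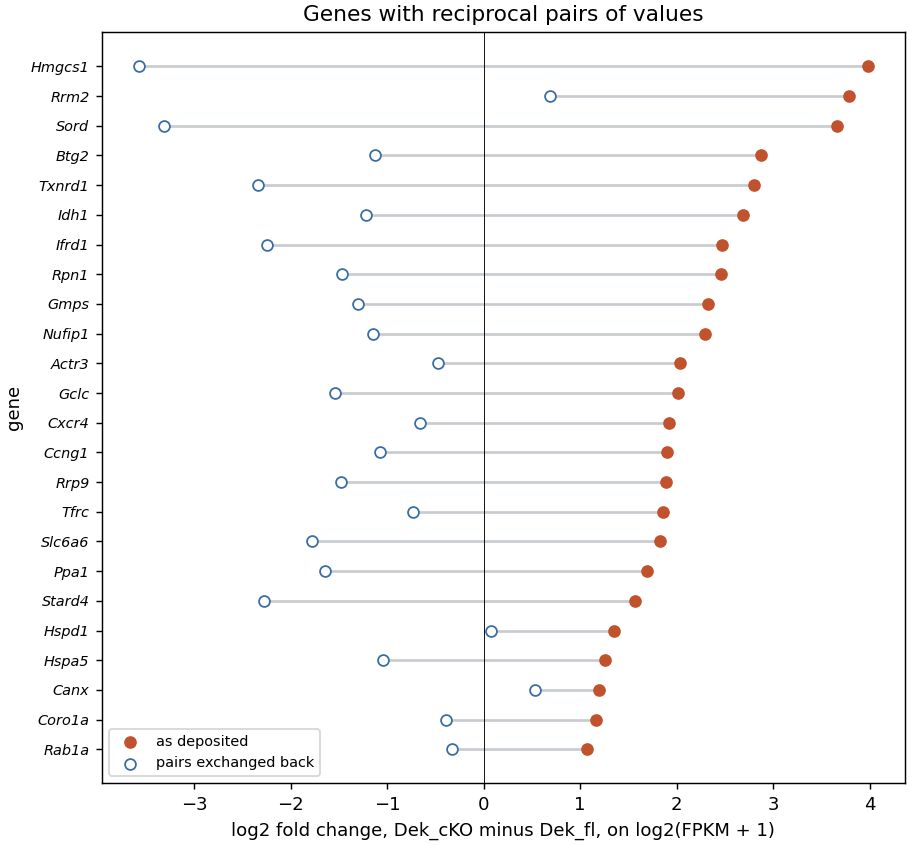
Log2 fold change of Dek_cKO minus Dek_fl on log2(FPKM + 1) (horizontal axis) for the 24 genes with reciprocal pairs of values (vertical axis). Filled points use the deposited values and open points the values with the pairs exchanged back, pairs with a value of 0 included. The median is 1.97 for the filled points and -1.18 for the open points.

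No gene was called higher or lower in Dek_cKO. Of 10260 genes tested by limma, 0 passed an adjusted p of 0.05, and the smallest adjusted p was 0.9999. At an unadjusted p under 0.05 there were 218 higher and 186 lower, against 513 that chance would give in all. Groups did not overlap in 507 genes (4.94%), where chance gives 5.71%. The median log2 fold change of all genes was 0.05 and its median SE was 1.25. In simulated libraries with the same spread, limma found 0 of 200 genes changed by 2 on the log2 scale and 56 of 200 changed by 4, among 10260 genes.

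The genes with the smallest unadjusted p among those without overlap are given as values, since none passed the threshold. On the lower side, Sil1, a nucleotide exchange factor of the endoplasmic reticulum on chromosome 18 (35266396 to 35499780), was at 32.9, 52.7, 34.4 and 177.9 FPKM in Dek_fl. In Dek_cKO it was listed at 0, 1.47 and 0, with a log2 fold change of -5.43 (SE 1.24). Lysmd2 on chromosome 9 (75625741 to 75637771) had a log2 fold change of -4.96 (SE 1.24). Tmem183a on chromosome 1 (134346097 to 134361979) had -4.42 (SE 1.19). Itpa, which hydrolyses inosine triphosphate, on chromosome 2 (130667610 to 130681614) had -4.57 (SE 1.30), and Tex30 on chromosome 1 (44086613 to 44102441) had -4.32 (SE 1.24). On the higher side, Tulp2 on chromosome 7 (45481877 to 45523632), Cdc42ep5 on chromosome 7 (4151260 to 4164860) and Zfp955b on chromosome 17 (33289544 to 33307241) were listed at 0 in all 4 Dek_fl libraries. In Dek_cKO their values were 51.3, 15.8 and 4.30 FPKM for Tulp2, 57.2, 60.9 and 2.18 for Cdc42ep5, and 55.4, 29.8 and 2.68 for Zfp955b. C2cd2l on chromosome 9 (44309237 to 44320285) had a log2 fold change of 3.57 (SE 1.06).

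None of the 8 genes chosen in advance passed the threshold by limma, and only in Akt1 did the groups not overlap. Akt1, a kinase that carries PI3K signals, on chromosome 12 (112653821 to 112674884), was at 39.3, 43.0, 59.5 and 33.8 FPKM in Dek_fl and 68.4, 85.4 and 98.2 in Dek_cKO, a log2 fold change of 0.94 (SE 0.760). Its values in Dek_fl replicate 1 and in all 3 Dek_cKO libraries are not whole reads. Akt2 on chromosome 7 (27591552 to 27640826) had a log2 fold change of 0.93 (SE 1.22; 0.29 without Dek_fl replicate 3 and 1.45 without Dek_fl replicate 1), with values in Dek_cKO replicates 1 and 2 that are not whole. Mtor, the kinase of the mTOR complexes, on chromosome 4 (148448611 to 148557683) had 0.10 (SE 1.16; -0.02 without Dek_fl replicate 1, 0.03 without Dek_cKO replicate 3 and 0.18 without Dek_fl replicate 4), and no transcript length made its values whole. Akt1, Akt2 and Mtor are named in the title of a paper on DEK in HSCs that may be the study of these libraries, so they are not independent evidence. The corepressor Ncor1 had a log2 fold change of -0.04 (SE 0.834), with a positive sign after TPM rescaling, with a replicate block and without Dek_fl replicate 3, Dek_fl replicate 4 or Dek_cKO replicate 3. The deacetylase Hdac3 had -1.63 (SE 1.24; -0.47 without Dek_cKO replicate 1 and -2.68 without Dek_cKO replicate 3). Among CDK inhibitors, Cdkn1a was at 43.3, 3.95, 10.7 and 32.1 FPKM in Dek_fl and at 5.93, 0 and 2.23 in Dek_cKO, with no length that made its values whole. Cdkn1c had -0.05 (SE 1.40), a sign that turned with median-of-ratios scaling (0.06), quantile normalization (0.06), without Dek_fl replicate 1 (0.33) and without Dek_cKO replicate 3 (1.58), while it was -1.13 without Dek_cKO replicate 1. The mitotic cyclin Ccnb2 had 1.46 (SE 0.83; 0.69 without Dek_fl replicate 4).

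None of the 29 gene lists fixed in advance was called. By camera with a preset correlation the smallest adjusted p was 0.258, for the immediate early and stress genes. With an estimated correlation the adjusted p was 0.927 for each list, and by fry it was 0.994 for each. Both were run only in the main test, with all libraries, and not under the alternatives. No member of any list passed over all genes, and 0 passed when adjusted over the list alone. The median, mean and camera direction differ in sign for the lists of apoptosis, autophagy, stem cell identity, niche receptors, progenitors, corepressors and T and NK cells. The counts of members that follow are at an unadjusted p under 0.05.

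Genes of stem cell identity and quiescence, 35 tested, had 0 higher and 1 lower (camera adjusted p = 0.906). The lower gene was Gata2, at 31.5, 73.1, 113.6 and 123.7 FPKM in Dek_fl and 7.52, 18.3 and 12.3 in Dek_cKO. With its values of 5 decimals multiplied by 10, its log2 fold change moved from -2.56 to -0.43. Esam, an adhesion molecule of HSCs, had 1.99 (SE 0.992; 1.003 without Dek_fl replicate 4). Niche and adhesion receptors, 28 tested, had none (adjusted p = 0.932), with Eng at 2.65 (SE 1.38) and Itgb3 at -2.39 (SE 1.26) on the log2 scale. Markers of multipotent progenitors, 20 tested, had none (adjusted p = 0.898), with Cd27 at -1.84 (SE 0.938; -0.56 without Dek_cKO replicate 1 and -2.93 without Dek_cKO replicate 2) and Muc13 at 0.86 (SE 0.718; 0.52 without Dek_cKO replicate 2 and 1.36 without Dek_cKO replicate 3).

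CDK inhibitors and pocket proteins, 10 tested, had 1 higher and 0 lower (camera adjusted p = 0.811), and 3 of the members have values that are not whole. The higher gene was Btg2, an antiproliferative p53 target, with a log2 fold change of 2.88 as deposited and -1.12 with its pairs exchanged back. Btg2 was also the leading member of the p53 and DNA damage list, 20 tested, with 1 higher and 0 lower (adjusted p = 0.811) and 3 members that are not whole. The genes of G1/S and DNA replication, 43 tested, had 1 higher and 1 lower (adjusted p = 0.811). These were Rrm2, a ribonucleotide reductase subunit, at 3.78 as deposited and 0.68 with a pair exchanged back, and Rfc2 at -1.69 (SE 0.769; -0.80 without Dek_cKO replicate 2). The G2/M genes, 41 tested, had 1 higher, Ndc80, at 3.24 (SE 1.29), and 0 lower (adjusted p = 0.811). Apoptosis regulators, 20 tested, had 1 lower, Casp9, at -2.93 (SE 1.39), while Bak1 was at 1.34 (SE 1.01; adjusted p = 0.898 for the list).

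Components of the PI3K, AKT and mTOR pathway, 41 tested, had 2 higher and 0 lower (camera adjusted p = 0.898). The 2 were Phlpp1, a phosphatase of AKT, at 2.57 (SE 1.13), and Rps6, at 0.76 (SE 0.363), whose values in Dek_fl replicate 1 and Dek_cKO replicate 1 are not whole. Of 33 members assessed for whole reads, 6 were not (18.2%), against 0.515% of other genes (Fisher's exact test, adjusted p = 4.52e-07). Transcripts known to be raised by mTORC1, 32 tested, had 4 higher and 1 lower (adjusted p = 0.315). The gene with the smallest p was Hmgcs1, an enzyme of sterol synthesis, at 3.98 as deposited. It was at -3.57 with its pairs exchanged back, 1 of them with a value of 0. Next was the glucose transporter Slc2a1 at -3.87 (SE 1.40). In this list 6 of 26 assessed members were not whole (23.1%; adjusted p = 1.94e-07, Fisher's exact test). Without the genes that are not whole its camera adjusted p was 0.892, and with the values put back it was 0.692 with the list lower. Putting values back could only lower the members it changed.

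Ribosomal proteins, 76 tested, had 4 higher and 0 lower (camera adjusted p = 0.527). Rpl36 was at 1.17 (SE 0.436) and Rpl19 at 1.11 (SE 0.421), and both have values that are not whole. The adjusted p of this list was 0.00405 without Dek_fl replicate 1, 9.38e-04 without Dek_fl replicate 4, 1.37e-05 without Dek_cKO replicate 1, 4.14e-07 with array weights and 3.11e-11 by voom. In the main test it was 0.927 at the estimated correlation between members, 0.627, which was not used under these alternatives. It was 0.873 without the members that are not whole. The list turned lower without Dek_fl replicate 2 (0.881), Dek_fl replicate 3 (0.7097) or Dek_cKO replicate 3 (0.666). Ribosome biogenesis factors, 24 tested, had none (adjusted p = 0.367, 0.0319 without Dek_cKO replicate 1 and 0.925 without Dek_cKO replicate 2). With all libraries the adjusted p was 0.927 at the estimated correlation of 0.106. Nop56 was at 1.54 (SE 0.828; 0.95 without Dek_fl replicate 1) and Rrp9 at 1.89 as deposited and -1.48 with its pairs exchanged back. The unfolded protein response, 21 tested, had none (adjusted p = 0.315). Its leading members were the chaperones Hspa5, at 1.26 as deposited and -1.04 exchanged back, and Canx, at 1.19 as deposited and 0.53 exchanged back. The antioxidant genes, 25 tested, had 1 higher and 1 lower (adjusted p = 0.898). Txnrd1, thioredoxin reductase, was at 2.80 as deposited and -2.34 exchanged back, and Gclm, of glutathione synthesis, was at -3.24 (SE 1.21).

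Energy metabolism showed no call. Nuclear-encoded respiratory chain subunits, 77 tested, and those encoded by mitochondrial DNA, 13 tested, had none, each with a camera adjusted p of 0.811. The mitochondrial list had 7.01e-04 without Dek_fl replicate 4, 0.0176 with array weights and 0.0114 by voom. In the main test it had 0.927 at the estimated correlation, 0.485, and it turned lower without Dek_fl replicate 3 (0.752). The nuclear list had 0.0243 with array weights and 0.0222 by voom. In the main test it had 0.927 at the estimated correlation, 0.267. It turned lower without Dek_fl replicate 2 (0.881), Dek_fl replicate 3 (0.850) or Dek_cKO replicate 3 (0.666). Uqcrfs1 was at -2.29 (SE 1.21; -0.04 without Dek_cKO replicate 2 and -3.51 without Dek_cKO replicate 3), Ndufc2 at -1.03 (SE 0.650), mt-Nd3 at 1.25 (SE 0.745) and mt-Nd4 at 0.46 (SE 0.474; 0.06 without Dek_cKO replicate 2, 0.19 without Dek_fl replicate 3, 0.28 without Dek_fl replicate 2, 0.84 without Dek_cKO replicate 3 and 0.90 without Dek_fl replicate 4). Glycolytic enzymes, 20 tested, had none (adjusted p = 0.811), with Aldoa at -0.81 (SE 0.499) and Hk1 at 2.21 (SE 1.37; 1.37 without Dek_cKO replicate 2, 1.45 without Dek_fl replicate 1 and 3.47 without Dek_cKO replicate 3). The mitochondrial biogenesis list, 25 tested, had 1 lower, Cs, the citrate synthase, at -2.58 (SE 1.04; adjusted p = 0.811), while Vdac1 was at -1.18 (SE 0.613; -1.79 without Dek_cKO replicate 1). Autophagy and lysosome genes, 31 tested, had 1 higher and 1 lower (adjusted p = 0.811), the lower being Map1lc3b at -2.04 (SE 0.924).

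Among chromatin genes, corepressors, deacetylases and acetyltransferases, 27 tested, had none (camera adjusted p = 0.886), with Sin3b at -2.31 (SE 1.17; -0.98 without Dek_cKO replicate 2) and Hdac10 at 2.74 (SE 1.50). Histones and their chaperones, 32 tested, had none (adjusted p = 0.811), with Hmga1 at -1.97 (SE 1.12; -0.37 without Dek_cKO replicate 2) and Hira at 1.05 (SE 0.759). Interferon-stimulated genes, 34 tested, had 2 higher, Stat2 at 3.93 (SE 1.36) and Ifit2 at 1.83 (SE 0.876), and 0 lower (adjusted p = 0.811). Immediate early and stress genes, 25 tested, had 2 higher, Ier3 at 3.27 (SE 1.07; 2.12 without Dek_fl replicate 4) and Btg2, whose values are not whole and which is lower with its pairs exchanged back, and 0 lower (adjusted p = 0.258). Without Dek_cKO replicate 2 the adjusted p of this list was 0.0462, and without Dek_cKO replicate 3 it was 0.038. It was 0.820 without Dek_cKO replicate 1. With all libraries it was 0.927 at the estimated correlation of 0.178.

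Markers of other blood and stromal cells were measured with the same test. Granulocyte and monocyte markers, 19 tested, had none (camera adjusted p = 0.317, 5.40e-04 without Dek_cKO replicate 1 and 0.0328 with array weights). In the main test the adjusted p was 0.927 at the estimated correlation of 0.127. The list turned lower without Dek_cKO replicate 3 (0.965), the library in which 11 of the 19 members were highest. With all libraries, 16 of the 19 had a positive log2 fold change, among them Camp at 2.57 (SE 1.32; 1.50 without Dek_fl replicate 4) and S100a8 at 1.50 (SE 0.919; 0.89 without Dek_fl replicate 3 and 2.47 without Dek_cKO replicate 1). The neutrophil elastase gene Elane, chosen after its values were seen, was at 5393 FPKM in Dek_cKO replicate 3 and at 0 to 983.9 in the others. Megakaryocyte markers, 13 tested, had 1 higher, Gp9, at 3.02 (SE 1.45; adjusted p = 0.811), while Treml1 was at 2.68 (SE 1.55; 4.30 without Dek_cKO replicate 1). Erythroid markers, 9 tested, had none (adjusted p = 0.686). Hbb-bs was at -2.13 (SE 1.32) and the transferrin receptor Tfrc at 1.86 as deposited and -0.73 exchanged back. The B-lineage list, 9 tested, had 1 lower, H2-Aa, at -3.55 (SE 1.2; adjusted p = 0.811), which encodes a class II histocompatibility chain, while Cd74 was at 1.39 (SE 0.994; 0.18 without Dek_fl replicate 1). The T and NK list, 4 tested, had 1 higher, Nkg7, at 1.57 (SE 0.748; 0.66 without Dek_fl replicate 4; adjusted p = 0.844), while Trbc2 was at 1.04 (SE 0.791; 1.74 without Dek_cKO replicate 1). Endothelial and stromal markers, 6 tested, had none (adjusted p = 0.811), with Pecam1 at 1.61 (SE 1.25) and Vcam1 at -1.40 (SE 1.14).

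**Figure D4:**
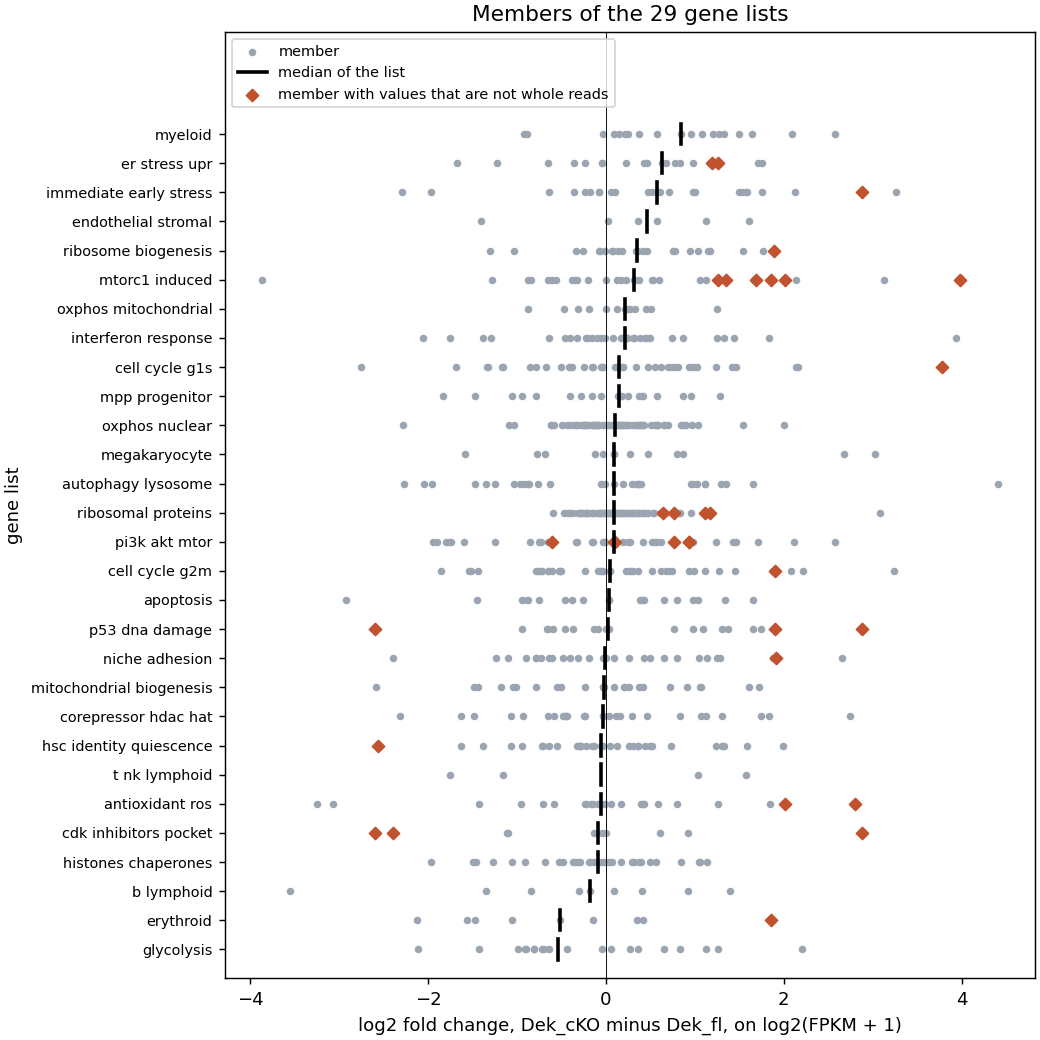
Log2 fold change of Dek_cKO minus Dek_fl on log2(FPKM + 1) (horizontal axis) for the tested members of the 29 gene lists (vertical axis, sorted by median). Grey points are members, diamonds are members with values that are not whole reads, and bars are list medians. No list passed an adjusted p of 0.05, and the myeloid list has the highest median, 0.84.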

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

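The tests of explanations in this part were chosen after the results were seen. Among the 4 Dek_fl libraries, 10 of 79 values had a library far from the others, with the gap to the nearest divided by the range above Dixon's critical value for 4 samples, where chance would give about 4 if values were normal. For Hdac10 and Trbc2 the other Dek_fl libraries are all listed at 0, which fixes the ratio at 1.0, and for Bak1, Stat2 and Treml1 they are below 0.33 FPKM, so the comparison with chance is not a fair one. The number of abundant genes listed at 0 had a ratio of 0.921, with Dek_fl replicate 4 the highest. Dek_fl replicate 1 was lowest for Hdac3 (0.884) and Cd74 (0.881) and highest for Bak1 (0.850), Stat2 (0.967) and Trbc2 (1.0). Dek_fl replicate 3 was lowest for Txnrd1 (0.922) and highest for Hdac10 (1.0) and Treml1 (0.936), and Dek_fl replicate 2 was highest for Muc13 (0.843). The value of Txnrd1 in Dek_fl replicate 3 is one of a reciprocal pair.

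The low gene number of Dek_fl replicate 4 was set against depth and library composition. Dek_fl replicate 1 had fewer reads in all, and fewer outside the 10 genes of most reads (3846001 against 3890393), although these took 13.95% of reads in Dek_fl replicate 4 and 8.63% in Dek_fl replicate 1. Dek_fl replicate 1 had 2.25 times as many genes above 0, which argues against depth and against a few genes taking the reads as the whole cause. In Dek_fl replicate 4, 101 abundant genes were listed at 0, more than in any other, which restates the low gene number, so capture of fewer molecules from the sorted cells and other causes of missing transcripts cannot be told apart. No biological explanation was tested, as the design names none within a group.

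The values that are not whole reads were weighed next. As a control for another transcript length, 541 genes were read at a wrong length, and 0 resolved by exchange. A control gene had to have every value that was not whole in a separate pair. With 7 libraries a gene with no whole value could not meet this, while any pair sufficed for the 24 genes. The control therefore does not decide on another length. The search for lengths does bear on it. With their own totals, no single length up to 3 times the annotated one made all values of any of the 24 genes whole. At the annotated length, 19 of the 24 were whole in all libraries after the exchange, Nufip1, Sord and Hmgcs1 only with a pair holding a 0. For these 19 genes the values argue against a single other length within the range searched. An exchange of whole libraries would carry each total along, since each total was fitted to the values of its own column. It would leave every gene whole, and so would not by itself give these pairs. The partner of a column also differed between genes. Dek_fl replicate 2 was paired with Dek_cKO replicate 2 in Ifrd1, replicate 1 in Ppa1 and replicate 3 in Slc6a6. This argues against an exchange of whole libraries as the source of the pairs. Whether whole columns carry the wrong label is a separate question, on which the 99.4% of genes that were whole do not bear. All 52 of 52 pairs joined columns of different groups, where 57.1% of possible pairs of libraries do. An exchange of single values between the columns of the 2 groups was proposed from these pairs, so they are no test of it, and it stays open. How such an exchange could have come about is not shown by the table, and no biological explanation was tested.

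Of the 42 genes, 24 have pairs with both values above 0, and Cfp has a pair only with a value of 0. Of the 17 genes without a pair, 11 have a length at which other values of the same gene are whole, while for 6 no length was found. The search took in unannotated whole-base lengths up to 3 times the annotated one, also with up to 2 values left out. A single length within that range therefore does not account for the values of these 6. A length beyond it cannot be told apart from another origin. All 3 values with 5 decimals, of Dek and Gata2, became whole when multiplied by 10, against 1 of 176 other values that are not whole, so a decimal point moved by 1 place is a candidate explanation for them.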

How the results depend on the processing

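The alternatives without the genes that are not whole, with values put back, with Dek multiplied by 10 and with voom were chosen after seeing the data. Under all 20 settings run for the counts, 0 genes passed an adjusted p of 0.05 by limma in either direction. The planned count tools were not run, because the deposited unit is FPKM. At an unadjusted p under 0.05, the 218 genes higher became 128 with the stricter filter, for which fewer genes were tested, and ranged from 155 to 238 when a library was left out. The 186 lower became 286 with array weights, and ranged from 96 without Dek_cKO replicate 2 to 346 without Dek_fl replicate 4, with 105 without Dek_fl replicate 3. The Dek difference of -80.7 FPKM kept its sign in all 11 settings, from -102.4 to -63.4 FPKM when a library was left out, and was -42.8 FPKM with the value of 5 decimals multiplied by 10. Of 638 values for gene lists, 621 stayed on their side of the threshold and 17 passed it, and 22 of the 29 lists changed direction in 65 values. Adjusted p-values by camera that passed were 0.0328 for the myeloid list, 0.0176 and 0.0243 for the mitochondrial and nuclear respiratory lists and 4.14e-07 for ribosomal proteins with array weights. With voom they were 0.0114, 0.0222 and 3.11e-11 for the last 3. At the estimated correlation each of these lists had 0.927, but this was computed only in the main test, not with array weights or voom. The cause was not tested. Leave-one-out ranges of the adjusted p were 0.038 to 0.820 for immediate early genes, 5.40e-04 to 0.965 for the myeloid list (lowest without Dek_cKO replicate 1), 7.01e-04 to 0.938 for the mitochondrial respiratory list (lowest without Dek_fl replicate 4), 1.37e-05 to 0.880 for ribosomal proteins and 0.0319 to 0.925 for ribosome biogenesis (both lowest without Dek_cKO replicate 1). Of the 71 named genes, 9 changed sign in 16 of 1361 values, 6 of them with pairs exchanged back, and none passed the threshold in any.

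Same-numbered libraries did not deviate together, with correlations of -0.03, -0.073 and 0.045 for numbers 1 to 3, and none of the 3 Dek_cKO libraries correlated best with its own number. With a replicate block, in which Dek_fl replicate 4 stands alone, 0 genes passed, 337 were lower at an unadjusted p under 0.05, and the adjusted p was 0.00485 for both the mitochondrial respiratory list and ribosomal proteins, against 0.927 for both at the estimated correlation without a block.

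With 4 against 3 libraries and a median residual SD of 1.51 on the log2 scale, changes of 2 on that scale were not detectable.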

Other observations

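All tests in this part were written after the results were seen, those over other splits of the libraries included, which follow a fixed rule. The genes of surface proteins used in the sort are given as values. Ly6a, which encodes Sca-1, was at 181.6 ± 88.9 FPKM in Dek_fl (SD, n = 4) and 151.3 ± 95.1 in Dek_cKO (SD, n = 3). Kit was at 91.6 ± 21.2 and 137.5 ± 112.7 FPKM. Slamf1, which encodes CD150, was listed at 0, 0, 0.0588 and 1.70 FPKM in Dek_fl and 0.456, 0 and 1.80 in Dek_cKO. Cd48, a gene of a protein the sort selects against, was at 145.8, 206.0, 146.5 and 4.10 FPKM in Dek_fl and 52.3, 7.82 and 135.1 in Dek_cKO. Ly6a, Kit and Cd48 were among the genes tested by limma, none of which passed the threshold, while Slamf1 did not pass the filter.

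Genes of primary granules stood highest in 1 library. Dek_cKO replicate 3 had 5393 FPKM of Elane, 1542 of Mpo, 1571 of Ctsg and 2019 of Prtn3, against at most 983.9, 448.8, 129.5 and 659.9 in the other 6. Of the other 15 tested members of the myeloid list, written before the data were examined, 7 were highest in this library. No other library had more than 3. The rule for support asked for more than 7 and was written after the results were seen. By this rule RNA of granulocyte-lineage cells is neither supported nor excluded. The sort removes lineage-positive cells, while committed progenitors may also carry these transcripts, and the table does not tell these apart.

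The counts were compared with the other splits of the 7 libraries into 4 and 3. The real split gave 0 genes past the adjusted threshold and 0 lists called by camera, and the highest others gave 3 genes and 7 lists. All 35 of 35 splits reach a count of 0, so these counts are no test of chance. For the 404 genes at an unadjusted p under 0.05, 25 of 35 splits gave as many, with 1077 in the highest other, so chance cannot be excluded for this count. The split with 1077 genes set Dek_fl replicates 1 and 4 and Dek_cKO replicate 2, the 3 libraries with the fewest reads, against the rest. It was picked as the highest of the 35, and whether it reflects a structure of the samples other than the group was not tested.

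The genes that lead the lists were often among those that are not whole. Of 55 genes named as the 2 of smallest p in a list, 42 were assessed for whole reads and 13 were not whole (31.0%), against 0.42% of other assessed genes (Fisher's exact test, one-sided, p = 3.66e-20). The leading genes were picked by p from these same values, and several lists hold a raised share of genes that are not whole. This p-value does not tell the choice by p apart from membership of a list.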
